A study of Mus musculus with 6 samples.

How the data were processed

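Total RNA from the aortic arch of ApoE-/- mice was measured on 6 single-colour Agilent mouse miRNA arrays, 3 from mice on regular chow and 3 from mice on chow with added methionine. Each array came from 1 sample, and the labels call the replicates of a diet biological. The title of high methionine replicate 3 carries T3 where those of replicates 1 and 2 carry T2, and what this marks is not given. The labels' age entry reads 25 weeks, whereas the protocol has 25 weeks of diet from 6 weeks of age, so the age at sampling is not settled. The scanner files hold spot intensity values that were made by the authors with Agilent Feature Extraction, version 10.7.3.1 per the file headers and 10.7 per the submitters' processing notes. The processed intensity had been background-subtracted within each array and not scaled between arrays, per the file headers. The headers name genome build mm9. The series text names another array maker than the scanner files do, and the labels' protocol describes a reverse-transcription labelling with Cy3, so the chemistry behind the signals is open. The authors' deposited table of log2 values was set against the scanner files. Each of its columns equals log2 of the total gene signal of its array minus 1 constant, to within 1.2e-05. The direction and log2 scale of that table are therefore settled, and how its constants were chosen stays unknown. Its column medians were -8.01, -7.93 and -8.53 for regular diet replicates 1, 2 and 3, and -8.35, -8.60 and -8.51 for high methionine replicates 1, 2 and 3. Between 901 and 955 of its 1157 entries lay at the column minimum.

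The arrays hold 45440 spots outside the controls, for 2889 probes of 1136 miRNA names, of which 1079 are mouse and 57 viral. Control spots were left out, and so were spots flagged as outliers by the scanner software (4.12% to 4.71% of spots per array). No spot outside the controls was saturated. The 10 to 40 spots of a probe were averaged on the linear scale. Signals were divided by each array's 75th percentile over the 197 probes well above background on all arrays. Values under a common floor of -5.05 on the log2 scale were then set to the floor, and log2 was taken. Of several probes of a miRNA, the one with the highest mean signal was used. Of 118 tested miRNAs with more than 1 detected probe, 9 had probes whose changes differed in sign. A miRNA was detected on an array where at least 50% of its probe's spots were well above background, and 197 miRNAs detected on at least 3 of the 6 arrays were tested, 3 of them viral. A miRNA not well above background on any array of a diet has only a bound there: its own signal, the lowest signal well above background on that array or the floor, whichever is highest, and its fold is written as at least that size. Names follow the array design, in which miR-143 stands for miR-143-3p and a star marks the minor arm. Coordinates are those of the probes on mm9 in the files. A gene table of assembly GRCm38 served only for names and for genes whose span holds a miRNA, and 184 of the 194 mouse miRNAs tested were found in it.

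The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 197 miRNAs and a threshold of 0.05. Camera, with a preset correlation between members, tested 21 lists written before the data were examined: smooth muscle contractile, smooth muscle proliferation, endothelial, leukocyte, erythroid, striated muscle, adipose, liver and plasma, epithelial, neuronal, extracellular matrix and fibrosis, cholesterol and lipid handling, DNA methyltransferase and homocysteine, flow sensitive endothelial, senescence with hypoxia and p53, let-7 family, the miR-17 cluster with its paralogs, miR-30 family, Dlk1-Dio3 imprinted cluster, Sfmbt2 intron cluster, and entries resembling fragments of other RNAs. Camera with an estimated correlation and fry were run beside it. The number of detected miRNAs was compared by an exact two-sided permutation test, whose smallest possible p with 3 arrays against 3 is 0.1. The named miRNAs were set by a rule written before the data were examined. It takes up to 10 miRNAs per direction past the threshold by size of change, or else up to 5 per direction with the smallest unadjusted p. It adds 15 preset miRNAs, members of each list past the threshold or else its 2 brightest, and the 3 brightest miRNAs. Of the preset miRNAs, 14 could be tested, and miR-33 was not detected often enough. Other miRNAs are named as examples of list members, or where chosen after their values were seen.

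Slide and scan day split the arrays in the same way. Slide 1 held regular diet replicates 1 and 2, and slide 2 held regular diet replicate 3 with all 3 high methionine arrays. Values with slide as a block are given beside the changes of named miRNAs and the list medians; because slide 1 held 1 diet, their size equals the comparison within slide 2, where the only regular diet array is assumed to vary like the others. Alternatives were no scaling, quantile normalization, normexp background correction with offset 50, total gene signal, the authors' deposited table, other detection filters, the mean over probes, another floor, a trended robust variance, array weights, the replicate number as a block, slide as a block, and leaving out each array. Added after the data were seen were slide as a random block, the comparison within slide 2, keeping outlier spots, the contractile list without miR-1a and miR-133a, and the DNA methyltransferase list without miR-143 and miR-133a.

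The fit was tested on simulated data with the means and spreads of the 197 miRNAs and 40 planted changes. In this comparison a planted change of 1 log2 unit was recovered in 7.25% of cases, of 2 log2 units in 38.6% and of 3 log2 units in 56.9%. Of the calls, 7.94%, 3.74% and 4.99% were false. In 50 simulations of the 21 lists with independent errors, a leukocyte shift of -1.5 was called in 100% of runs, and some list was called in 6% of runs with no shift. In the real data the estimated correlation between members was 0.76 for the leukocyte list and 0.99 for the Sfmbt2 intron cluster list. These percentages therefore do not give the error rate of camera in the real data. The number of arrays limits the precision of every value.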

Results

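The miRNA content of the aortic arch was measured in ApoE-/- mice, which lack apolipoprotein E and develop atherosclerosis. Per the treatment protocol, the mice were fed from 6 weeks of age for 25 weeks on chow with 0.37% methionine or on the same chow with 1.7% methionine added. Methionine is a dietary precursor of homocysteine. There were 3 arrays for each diet. The 75th percentile of signal over probes detected on all arrays was 473 and 506 on the slide with regular diet replicates 1 and 2, and between 622 and 909 on the slide with regular diet replicate 3 and the high methionine arrays. The brightest entries on average were miR-3963 (4.01 over all arrays on the log2 scale), miR-720 and miR-5100, and miR-451, miR-29a, let-7b and let-7c also stood among the brightest 10.

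The first comparison asked whether the number of detectable miRNAs differed between the diets. On regular diet 183 ± 20.2 miRNAs were detected (SD, n = 3) and on high methionine 196 ± 12.1 (SD, n = 3). The difference of 13 did not exceed the spread between arrays (exact permutation test, n = 3 per group, p = 0.4, smallest possible 0.1). The arrays on slide 1 had 165 and 180 detected miRNAs, while regular diet replicate 3 on slide 2 had 205, against 195, 185 and 209 for the high methionine arrays beside it. Without regular diet replicate 1 the difference was 3.83, and without regular diet replicate 3 it was 23.8.

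The second comparison asked which miRNAs differed in level between the diets. At the small end of the p-values for higher signal stood 3 miRNAs known from red blood cells. The bicistronic pair miR-144 and miR-451 (chromosome 11, probes at 77886550 to 77886568 and 77886689 to 77886709 in mm9) had 3.26 and 2.70 times the regular diet signal on high methionine. The third, miR-3107 (chromosome 8, 24253067 to 24253080), which the gene table lists also as mir-486b inside the span of Ank1, had a ratio of 2.95. The fixed erythroid list names miR-486 and miR-486b-5p, which were not matched to the array's name miR-3107, so miR-3107 was not among its tested members. The fixed striated muscle list names miR-486 too and also lacked it. Neither list was tested with miR-3107 added. As tested, the erythroid list did not pass (camera adjusted p = 0.215). Its members miR-16 and miR-15b had changes of 0.14 and -1.34, or 0.22 and -0.26 with slide as a block. At the small end for lower signal stood miR-155, a miRNA of activated leukocytes (chromosome 16, 84714394 to 84714410), at 0.239 times the regular diet signal. No single miRNA passed the test, so these are values and not calls.

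By limma, 0 of 197 miRNAs passed an adjusted p of 0.05 in either direction. The smallest adjusted p was 0.19. At an unadjusted p under 0.05 there were 39 miRNAs, 18 with higher and 21 with lower signal, where chance gives 9.85. With array weights, a fit that gave regular diet replicate 2 a weight of 0.172, limma called 41 miRNAs. With slide as a block the count was 0, with 5 at an unadjusted p under 0.05. Within slide 2 alone 1 regular diet array is left, so the spread there is that of the high methionine arrays. For some miRNAs, such as miR-672, those arrays all lay at the floor. The ranges of the diets did not overlap for 59 miRNAs, which is 29.9%, where chance gives 10%. Without regular diet replicate 3 limma called 23 miRNAs, a fit in which diet and slide coincide, and without high methionine replicate 1 it called 2, miR-34b-5p and miR-34c. Regular diet replicate 3 lay below both arrays of slide 1 for all 21 miRNAs with lower signal and above both for 12 of the 18 with higher signal; over all tested miRNAs it lay outside that pair for 74.1%.

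**Figure D1:**
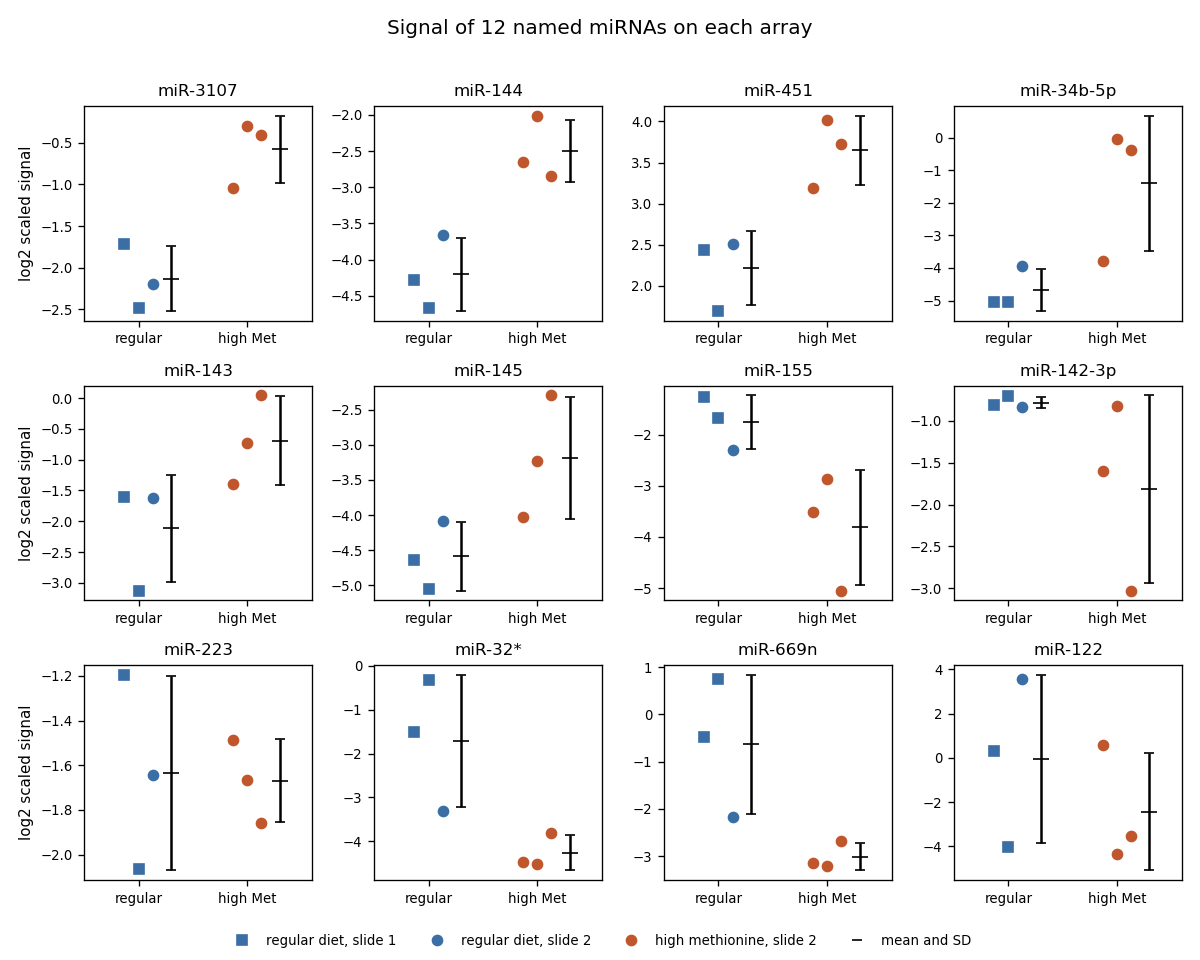
Log2 scaled signal (y axis, no unit) of 12 named miRNAs on the 6 arrays, by diet (x axis), with squares for slide 1, circles for slide 2, and bars for the mean and SD of 3 arrays. For miR-32* and miR-669n regular diet replicate 3, the only regular diet array on slide 2, lies between the slide 1 arrays and the high methionine arrays, and for miR-3107 it lies among the regular diet arrays.

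Of the miRNAs named by p, miR-144 had log2 signals of -4.20 ± 0.51 on regular diet and -2.50 ± 0.43 on high methionine (SD, n = 3), a change of 1.70 ± 0.38 (SE, limma adjusted p = 0.19), and of 1.16 with slide as a block. For miR-451 the signals were 2.21 ± 0.45 and 3.65 ± 0.42, a change of 1.43 ± 0.37 (SE), and of 1.13 with the block. For miR-3107 they were -2.14 ± 0.39 and -0.58 ± 0.40, a change of 1.56 ± 0.35 (SE), and 1.62 with slide as a block. The p53 target miR-34b-5p (chromosome 9, 50911682 to 50911702) had a change of 3.28 ± 1.03 (SE), and of 2.53 with the block. On regular diet it was detected on 1 of 3 arrays and lay at the floor on replicates 1 and 2, so the first of these is in part measured from the floor. Its signal was -0.04 and -0.36 on high methionine replicates 2 and 3, and -3.79 on replicate 1. The fifth, miR-129-5p, lay at the floor on every regular diet array, so its change of 0.73 is measured from the floor, with and without the block. Among those with lower signal, miR-155 went from -1.75 ± 0.52 to -3.81 ± 1.12 (SD, n = 3), a change of -2.06 ± 0.62 (SE), and of -1.51 with slide as a block. It was detected on 2 of 3 high methionine arrays and lay at the floor on replicate 3, so the floor limits the size of both values. The other 4 were miR-32*, miR-669n, miR-468 and miR-1196, with changes of -2.55, -2.38, -2.41 and -1.78. The slide block gave -0.95, -0.83, -0.79 and -0.66.

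The third comparison asked whether groups of related miRNAs moved together. By camera, 5 of 21 lists passed: the contractile smooth muscle list and the list tied to DNA methyltransferases and homocysteine rose on high methionine, and the leukocyte list, the list of the miR-17 cluster with its paralogs and the Sfmbt2 intron cluster list fell. With an estimated correlation no list passed, and each of these 5 had an adjusted p = 0.776 with an estimated correlation. Fry passed 0 lists, with a smallest adjusted p of 0.283 and 0 at an unadjusted p under 0.05. Members that did not pass limma's test on their own are given as values.

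The contractile smooth muscle list rose, with a median log2 change of 1.41 over 6 tested members (camera adjusted p = 0.00899, and adjusted p = 0.776 with an estimated correlation). All 6 members had higher signal, 0 passed over all miRNAs and 0 when adjusted over the list alone. The pair miR-143 and miR-145, hallmarks of contractile smooth muscle, lie in the span of Carmn on chromosome 18 (61808895 to 61808909 and 61807495 to 61807507). For miR-143 the change was 1.43 ± 0.57 (SE), from -2.12 ± 0.87 to -0.69 ± 0.72 (SD, n = 3), and for miR-145 it was 1.40 ± 0.51. With slide as a block these were 0.93 and 0.89. On regular diet miR-145 was detected on 1 of 3 arrays and lay at the floor on replicate 2. The members miR-23b and miR-27b had changes of 0.92 and 1.00 (0.37 and 0.40 with the block). Muscle miRNAs also in this list, miR-1a and miR-133a, had changes of 2.27 and 1.99 (2.26 and 2.20 with the block). Both lay at the floor on regular diet replicate 2, so their changes over all arrays are in part measured from the floor. Other detected probes gave 0.59 for miR-133a, 0.94 for miR-145, 0.64 for miR-27b, 1.54 for miR-143 and 1.01 for miR-23b. Without miR-1a and miR-133a, the list kept a median of 1.20 (camera adjusted p = 0.0324). With slide as a block the list median was 0.91 (camera adjusted p = 0.0225), and within slide 2 its adjusted p was 0.00543. Without regular diet replicate 2 the median was 0.86, and without regular diet replicate 3 the call was lost (median 1.67, camera adjusted p = 0.0545).

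The leukocyte list fell, with a median log2 change of -1.44 over 7 tested members, all with lower signal (camera adjusted p = 0.00899, and adjusted p = 0.776 with an estimated correlation). No member passed on its own, and 0 did when adjusted over the list alone. On high methionine replicate 3, miR-155, miR-142-5p and miR-150 lay at the floor. The floor therefore limits the size of their changes and of the list median. After miR-155, the T and B cell miRNAs miR-342-3p and miR-150 had changes of -1.55 ± 0.56 and -1.44 ± 0.66 (SE), or -1.14 and -1.63 with slide as a block. The pan-leukocyte miR-142-3p had a change of -1.03 ± 0.57 (-0.99 with the block), with -0.82 on high methionine replicate 2 and -3.03 on replicate 3. The myeloid miR-223 had a change of -0.035 ± 0.32 (-0.028 with the block). Other detected probes gave -0.89 for miR-150, -0.79 for miR-142-3p, -1.39 for miR-142-5p, -1.44 for miR-342-3p and 0.27 for miR-223. With slide as a block the list median was -1.18 (camera adjusted p = 0.0305), and within slide 2 the call was lost (adjusted p = 0.417). Without regular diet replicate 3 the call was lost (median -1.35, camera adjusted p = 0.0545), and without high methionine replicate 3, whose title differs from those of the other 2 arrays of its diet, the median was -0.78.

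The list tied to DNA methyltransferases and homocysteine rose, with a median log2 change of 0.84 and higher signal in 11 of 12 tested members (camera adjusted p = 0.00899, and adjusted p = 0.776 with an estimated correlation). No member passed on its own or when adjusted over the list alone. It holds miR-152 and miR-148a, which target Dnmt1, with changes of 0.82 ± 0.36 and 0.93 ± 0.68 (SE), and miR-125b-5p with 0.86 ± 0.37; with slide as a block these were 0.30, 0.18 and 0.28. Of the miR-29 family, which targets Dnmt3a and Dnmt3b, miR-29a had a change of -0.018, miR-29b 0.70 and miR-29c 0.89, or -0.25, -0.044 and -0.067 with the block. The largest changes in the list were those of miR-133a and miR-143, which the contractile list holds too, and without them the median was 0.78 (camera adjusted p = 0.0274). The call was lost with slide as a block (median 0.17, camera adjusted p = 0.135) and within slide 2 (adjusted p = 0.138), and it was also lost without regular diet replicate 2 (median 0.56, camera adjusted p = 0.0642).

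The Sfmbt2 intron cluster list, repeat-derived miRNAs of which members of the miR-466 and miR-669 families were tested, fell with a median log2 change of -2.19 over 8 tested members, all with lower signal (camera adjusted p = 1.40e-04, and adjusted p = 0.776 with an estimated correlation). On high methionine 6 of the 8 lay at the floor on at least 2 arrays, so the floor limits the size of this median and of its slide-block value. Clear of the floor were miR-669n and miR-466i-5p, with changes of -2.38 and -1.60, or -0.83 and -0.57 with the block. By limma 0 members passed over all miRNAs and 6 passed when adjusted over the list alone. Of the 8, 6 lie by the gene table within Sfmbt2 on chromosome 2. For miR-669o-5p, which was not well above background on any high methionine array, regular diet signal was at least 3.26-fold higher, a bound that was 1.95-fold without regular diet replicate 2, and its change with slide as a block was -0.054. The probes of all 8 hold a CA repeat, and 9 tested miRNAs outside the list whose probes hold one too had a median change of -1.72, and of -0.60 within slide 2. The call was lost with slide as a block (median -0.56, camera adjusted p = 0.102). Within slide 2 the median was the same, against 1 regular diet array. There miR-669e, miR-669b and miR-669o-5p lay at the floor on all 3 high methionine arrays, with an SD of 0. A test within slide 2 therefore rests in part on values without spread. Regular diet replicate 3 lay 2.46 below the slide 1 arrays in the list's median difference. Without regular diet replicate 2 the median was -1.46.

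The list of the miR-17 cluster with its paralogs, which includes many miRNAs of proliferating cells, fell with a median log2 change of -0.88 over 9 tested members, all with lower signal (camera adjusted p = 0.0274, and adjusted p = 0.776 with an estimated correlation). No member passed on its own or when adjusted over the list alone. For miR-92a the change was -1.32 ± 0.48 and for miR-19b -0.88 ± 0.41 (SE), or -0.52 and -0.50 with slide as a block. The median with the block turned to 0.015 (camera adjusted p = 0.881), and within slide 2 the list did not pass (adjusted p = 0.655). The call was lost without regular diet replicate 2 (median -0.27, camera adjusted p = 0.55) and without high methionine replicate 1 (median -0.92, camera adjusted p = 0.0935).

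**Figure D2:**
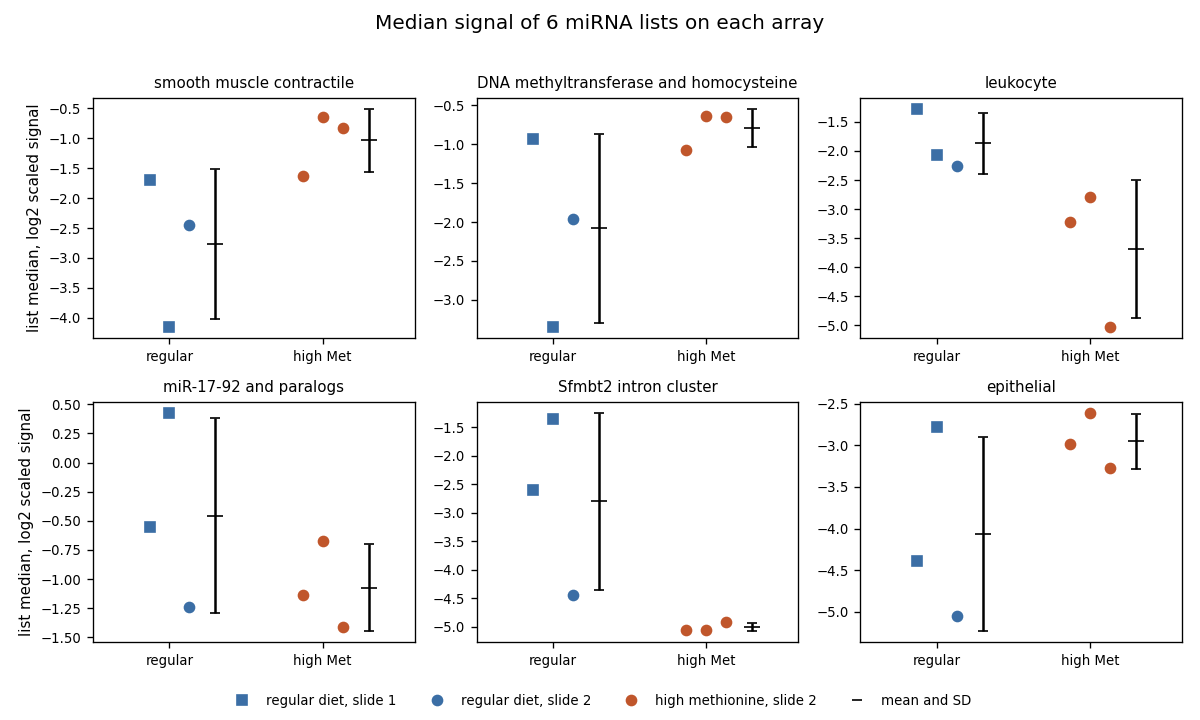
Median log2 scaled signal (y axis, no unit) of the tested members of 6 lists on the 6 arrays, by diet (x axis), with squares for slide 1, circles for slide 2, and bars for the mean and SD of 3 arrays. The leukocyte medians of the high methionine arrays lie between -5.04, next to the floor of -5.05, and -2.79. Those of the regular diet arrays lie between -2.26 and -1.27. For the miR-17 cluster regular diet replicate 3 at -1.24 lies among the high methionine arrays.

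The other 16 lists did not pass camera. Adipose miRNAs came closest, with a median change of 1.36 (camera adjusted p = 0.0537), and miR-193b, miR-378 and miR-378* passed when adjusted over the list alone, with 2.82, 2.76 and 2.73 times the regular diet signal on high methionine. The slide block gave a list median of 0.61 (camera adjusted p = 0.077) and changes of 0.94, 0.57 and 0.66 for these miRNAs, and without high methionine replicate 1 the list passed (median 1.55, camera adjusted p = 0.0219). Striated muscle miRNAs had a median change of 2.13 (camera adjusted p = 0.1), with miR-133b at 2.35 ± 1.22 (SE), or 2.28 with the block. Another probe of miR-133b gave 1.21. The striated muscle median was 1.26 without regular diet replicate 2 (camera adjusted p = 0.108), and without regular diet replicate 1 the list passed (median 3.18, camera adjusted p = 0.00255). The erythroid list had a median of 0.51, or 0.15 with miR-144*, seen on no regular diet array, at its bound of at least 1.11-fold higher signal, which was 0.976-fold without high methionine replicate 2 (camera adjusted p = 0.215), and miR-144 and miR-451 passed when adjusted over the list alone, while miR-15b had a change of -1.34 ± 0.57 (SE), or -0.26 with the block. Medians were 0.66 for the miR-30 family, 0.90 for the matrix list and 0.75 for the cholesterol list, in which miR-144 passed when adjusted over the list alone (camera adjusted p = 0.1, 0.1 and 0.175). The matrix list passed without regular diet replicate 1 (median 1.00, camera adjusted p = 0.0268), and without regular diet replicate 2 its median was 0.35 (camera adjusted p = 0.448). With slide as a block the medians of these 3 lists were 0.048, -0.027 and 0.18 and did not pass. The striated muscle and erythroid lists passed with the block, with medians of 2.23 and 0.51 (camera adjusted p = 0.0305 and 0.0352). That erythroid median is the change of miR-144*, which lay at the floor on every regular diet array, so it is measured from the floor. Within slide 2 the striated muscle list passed (adjusted p = 0.00543) and the erythroid list did not (adjusted p = 0.119).

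Liver miRNAs varied widely between arrays of the same diet. The hepatocyte miRNA miR-122 (chromosome 18, 65408523 to 65408541) had log2 signals of 0.32, -4.00 and 3.55 on regular diet and 0.58, -4.34 and -3.53 on high methionine, a change of -2.39 ± 2.15 (SE), and of -5.98 with slide as a block. The liver and plasma list had a median change of -1.92 (camera adjusted p = 0.46) and of -3.12 with the block, where it passed (camera adjusted p = 0.04998), and did not pass within slide 2 (adjusted p = 0.27). Epithelial miRNAs had a median change of 0.50 (camera adjusted p = 0.342), with 1.29 ± 0.65 for miR-200b and 0.50 ± 0.99 for miR-200c (SE), or 2.49 and 2.63 with slide as a block. On slide 2 the epithelial median was 1.89, measured from the floor of a single array, since the list median of regular diet replicate 3 was -5.05 with all members but miR-375 at the floor, and the list passed with the block (camera adjusted p = 1.12e-04) and within slide 2 (adjusted p = 5.52e-04). Without regular diet replicate 2 it passed as well (median 1.49, camera adjusted p = 0.00498).

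Vessel wall lists outside the contractile group did not pass. The endothelial miR-126-3p had a change of 0.94 ± 0.67 (SE) and -0.056 with slide as a block, and miR-21, which is abundant in injured vessels, had -0.0023 ± 0.38, or -0.27 with the block. For miR-126-3p the signal was -1.16 on regular diet replicate 2, and 0.90 and 1.36 on replicates 1 and 3. On high methionine it lay between 1.10 and 1.42. Medians were 0.34 for the endothelial list (mean -0.093), 0.43 for smooth muscle proliferation, -0.0023 for the flow sensitive list, 0.25 for let-7, and -0.11 for senescence with hypoxia and p53 (mean 0.18); with slide as a block they were -0.086, -0.27, -0.056, -0.10 and -0.18. The neuronal list had a median of 0.11 (mean -0.31), with -1.77 ± 1.44 (SE) for miR-128, and the entries resembling RNA fragments one of 0.067; with the block the medians were -0.0091 and 0.0057 and miR-128 had -0.0091. Their camera adjusted p-values ran from 0.542 to 0.998. Of the brightest list members, let-7b and let-7c had changes of 0.12 and 0.27, miR-22 and miR-34a 0.85 and -0.54, miR-24 and miR-26a 0.73 and 0.43, miR-27a 0.75, miR-30a and miR-30e 0.66 and 0.62. The block gave, in the same order, -0.066, -0.14, -0.12, -0.25, 0.40, -0.20, 0.32, -0.14 and 0.049. For the Dlk1-Dio3 cluster the median was 0.070 (camera adjusted p = 0.998) and -0.88 with slide as a block, where it passed (camera adjusted p = 0.04998; within slide 2, where it did not, adjusted p = 0.417), and its members miR-494 and miR-3072* had changes of 0.53 and -0.36 (0.22 and -0.54 with the block). The bright entries miR-3963, miR-720, miR-5109 and miR-5100 had changes of 0.43, 0.026, 0.081 and -7.4e-04, and miR-466i-5p, the brightest of its list, one of -1.60. With the block these were -0.57, -0.25, 0.24, -0.40 and -0.57.

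**Figure D3:**
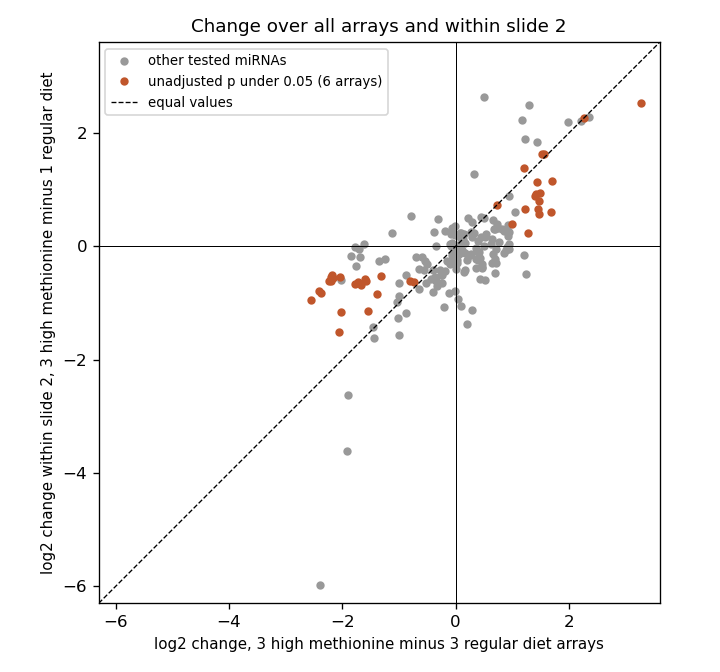
Log2 change of each of the 197 tested miRNAs over all 6 arrays (x axis) against its log2 change within slide 2, where 3 high methionine arrays face 1 regular diet array (y axis); orange points have an unadjusted p under 0.05 over all arrays and the dashed line marks equal values. The median size of change is 0.64 over all arrays and 0.40 within slide 2, and the orange points with lower signal lie nearer to 0 on the y axis.

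The arrays themselves differed within the regular diet group. Over the 197 miRNAs regular diet replicate 2 correlated with the other arrays at r between 0.672 and 0.829 (across miRNAs, which are not independent replicates), while the other pairs lay between 0.844 and 0.97. On that array 7 miRNAs lay at least 2 log2 units above every other array. They were miR-128, miR-130b, miR-181a, miR-181b, miR-18a, miR-20b and miR-205. The first principal component held 59.3% of the variance and set this array apart. Labelling control signal was 212 and 268 on slide 1 and between 477 and 556 on slide 2, so the slides differed in more than the mice they carried. By the scanner software, the hybridisation control was out of range on regular diet replicates 1 and 2 and in range on every slide 2 array. The labelling control was out of range on regular diet replicate 1 alone.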

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

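The alternatives chosen after the data were seen were slide as a random block, the comparison within slide 2, kept outlier spots, the contractile list without miR-1a and miR-133a, and the DNA methyltransferase list without miR-143 and miR-133a. By limma the count of miRNAs was 0, with 39 at an unadjusted p under 0.05, and it stayed 0 except in these fits: 4 with the authors' deposited table (miR-144* and miR-149* higher, miR-195* and miR-342-5p lower), 41 with array weights (17 higher, 24 lower; the weight estimation stopped before converging), and 0 to 23 when leaving out each array. In the deposited table the changes of miR-144*, miR-149*, miR-195* and miR-342-5p were 6.16, 5.18, -7.62 and -5.09. That fit took entries at the column minimum as values, so such sizes can be steps from that minimum. For miR-144*, detected on no regular diet array, the main fit gave a change of 0.51. Of the 23 miRNAs called without regular diet replicate 3, 21 were among the 41. Over the alternatives the smallest adjusted p ran from 0.0025 to 0.857. Camera called 5 lists; it called 2 with the deposited table, 8 with no detection filter, 3 with miRNAs detected on all 6 arrays, 1 with array weights, 7 with slide as a block, 4 within slide 2 and 3 to 7 when leaving out each array. With an estimated correlation it called 0, and fry called 0. Both of these allow for the correlation between members, and for the other changes the cause was not tested.

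With an estimated correlation all 5 lists lost their call (adjusted p = 0.776), as with fry. Of their other alternatives, the contractile list kept its call in 19 of 23 (adjusted p from 0.00114 to 0.109), the leukocyte list in 19 of 22 (9.49e-09 to 0.417), the DNA methyltransferase list in 18 of 23 (0.00255 to 0.138), the miR-17 cluster in 15 of 22 (4.23e-11 to 0.881) and the Sfmbt2 list in 20 of 21 (1.84e-08 to 0.102). The median of the Sfmbt2 list ran from -4.86 to 0 over its 21 alternatives. With slide as a block, and equally within slide 2, signs turned for miR-126-3p (-0.056), miR-29b (-0.044), miR-26a (-0.20), miR-22 (-0.12), miR-30a (-0.14), the miR-17 cluster list (0.015) and, with the block, the Dlk1-Dio3 list (-0.88). These slide fits use regular diet replicate 3 as the only regular diet array. Without scaling miR-3072* turned to 0.10, and the cause was not tested. A turn was counted where the value exceeded its standard error or a call was involved; of 1090 values of 50 named miRNAs, 1013 kept their sign and side of the threshold, 21 passed it and 45 others changed sign within 1 standard error of 0. The median log2 change of all tested miRNAs was 0.053. It was 0.45 without scaling, 0.19 with quantile normalization, 0.14 with normexp and 0.52 in the deposited table. The middle of the changes therefore lay higher in those fits, and single miRNAs need not be shifted by the same amount. The deposited table also had another tested set, of 233 miRNAs.

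With the replicate number as a block limma called 0 miRNAs, with 46 at an unadjusted p under 0.05, and camera 5 lists. Residual correlations of samples with the same number were -0.031, 0.29 and -0.0032. Regular diet replicates 1 and 3 did not correlate best with their own number. With 3 arrays per diet these values cannot tell whether the numbers pair the samples. Scaling by the 75th percentile of all probes gave no values, because that percentile was -1.64 on regular diet replicate 1. The share of miRNAs above background limits the data: 197 of 1136 could be tested.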

Other observations

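The tests of the 3 patterns below and the split count at an unadjusted p were chosen after the results were seen; for the contractile and leukocyte lists, the test without regular diet replicate 2 was divided by list, and its outcome for the contractile list reworded, once its values were known. The miRNAs in this paragraph and the next were also chosen after their values were seen. The linked miR-34b-5p and miR-34c (chromosome 9, 50911682 to 50911702 and 50911155 to 50911173) were high on 2 of 3 high methionine arrays. Their log2 signals were -0.043 and -1.58 on high methionine replicate 2 and -0.36 and -1.89 on replicate 3, against -3.79 and -5.05 on replicate 1, and miR-34c lay at the floor of -5.05 on all regular diet arrays.

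The muscle miRNA miR-133a and the epithelial miRNA miR-200c differed between arrays of the same diet. For miR-133a the log2 signals were -0.088, -5.05 and -2.88 on regular diet and -1.21, -0.11 and -0.73 on high methionine. For miR-200c the signals were -2.76, -0.93 and -5.05 on regular diet and -2.37, -2.10 and -2.78 on high methionine.

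The Sfmbt2 intron cluster list was lower on high methionine. Cross-hybridisation by probes with a CA repeat may account for its breadth: 9 miRNAs outside the list with such probes had a median change of -1.72 against 0.12 for 180 others, a difference of -1.84 (permutation p = 7e-05, 100000 resamples), and within slide 2 the median of the 9 was -0.60. Of these 9, miR-206 and let-7b were not lower. The permutation shuffled miRNAs as if they were independent, so its p-value measures no spread between arrays. Some of the 9, such as miR-32* and miR-468, had already been named for lower signal when the test was chosen. A slide difference cannot be told apart from diet here, because slide 2 holds 1 regular diet array, and with slide as a block the median was -0.56. The call was lost under the block, and also with an estimated correlation (camera adjusted p = 0.776). An effect of diet stays open.

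Regular diet replicate 2 stood apart from the other arrays. Weaker signal there is argued against as the source of the higher miRNAs by 7, part of what set the array apart, that lay at least 2 log2 units above every other array and by 1.84 to 4.35 before scaling; for the lower ones it stays open, since 26 lay at least 1 log2 unit below every other array, against 0 to 8 elsewhere, while the 75th percentile of signal was lower on regular diet replicate 1. RNA from thymocytes in that sample may be a source: all 5 listed thymocyte miRNAs not used to notice the pattern were highest on that array, by 1.24 for miR-20a, 1.14 for miR-19b, 0.88 for miR-92a, 0.81 for miR-15b and 0.11 for miR-142-3p. All 5 were detected on every array, and 3 are also in the list of the miR-17 cluster with its paralogs. Those 3, miR-20a, miR-19b and miR-92a, lie beside miR-18a on chromosome 14, and miR-18a was used to notice the pattern. They are therefore not a separate check. The T cell miRNAs miR-150 and miR-342-3p were not higher there, with -3.42 and -0.27 against -1.66 and 0.68 on regular diet replicate 1. Of the 7, miR-205 belongs to the epithelial list and not to the thymocyte list, and lay 2.39 above every other array. The share of all tested miRNAs that were highest on that array was not counted. No biological explanation by diet was tested.

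The contractile list was higher and the leukocyte list lower on high methionine, calls that both lists lost with an estimated correlation (adjusted p = 0.776). The other leukocyte miRNAs minus miR-223 differed by -1.76 ± 0.63 (SE, exact permutation p = 0.1, the smallest possible with n = 3 per group), so miR-223 did not fall with them. On slide 2 that value was -0.62 on regular diet replicate 3 and -1.76, -1.16 and -3.19 on the high methionine arrays. The miR-223 signal was known when the test was chosen and is that of 1 miRNA, so the test cannot exclude fewer leukocytes of every kind. Regular diet replicate 2 alone is argued against for the leukocyte list, whose median without it was -1.52; for the contractile list that median fell to 0.86 while the call with the preset correlation was kept, so its share in the pattern stays open. A slide difference cannot be told apart, because slide 2 holds 1 regular diet array, and with slide as a block the contractile median was 0.91. Fewer lymphocytes or less activated leukocytes on high methionine, and more contractile muscle in the samples, stay open as untested.

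There are 10 splits of the 6 arrays into groups of 3, too few for a share under 0.05. By limma the count past the threshold was 0 in all 10, so the highest other was 0. At an unadjusted p under 0.05 the real split gave 39 miRNAs, in 1 of 10 splits, and the highest other 13. Camera called 5 lists in the real split, as many or more in 4 of 10 splits, and 7 at most in the others. That split put regular diet replicates 1 and 2 with high methionine replicate 1 and so followed slide 1 in part; with slide as a block the real diets gave 7 lists.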
